A study of Rattus norvegicus with 105 samples.

How the data were processed

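Messenger RNA was measured in hippocampus and cerebellum of male Wistar Han rats after a closed-head weight-drop injury, on 105 two-colour Agilent arrays, 61 of hippocampus and 44 of cerebellum. Per the labels, a 500 g slug fell from 100 cm for mild and from 120 cm for moderate injury, and tissue was taken 6 h, 48 h or 14 d later. All sample titles and injury labels of both severities also carry the suffix NS, whose meaning is not given in the sources used here. Each array carried 1 animal's RNA labelled with Cy5 and a universal rat reference RNA, pooled from cell lines, labelled with Cy3, with no dye swap. All ratios below are sample over reference, so a dye bias shared by the arrays cancels only in differences between groups. The arrays came from 63 animals, of which 42 gave both tissues. Groups were taken from the labels, and the animal numbers from the sample titles.

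The deposited scanner files hold spot intensity values on a linear scale, the median pixel brightness of each of 62976 spots and of its local background in both channels, written by Agilent Feature Extraction per the file headers. The headers name version 12.0.3.1 for the hippocampus arrays and 10.7.1.1 for the cerebellum arrays, while the submitters' processing notes name version 10.7. The deposited files also hold the scanner software's own dye-normalised log10 ratio, and the authors' processed table of the series holds log10 values. Each value of that table lay within a relative difference of 0.00498 of the array's own log10 ratio, so the table is the same quantity rounded, in the same direction and with no further centring, and is not independent of it. As alternatives, the scanner's log ratio was centred on each array's median here and the authors' table was used as it stands, so the 2 settings differ in that centring. The medians of its arrays ran from -0.0289 to 0.00156 in hippocampus and were 0 in cerebellum. All its columns matched a labelled sample.

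From the deposited intensity values, background was corrected with normexp (offset 50) and ratios were normalised by loess within each array in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8) and Python 3.11.15 for tables and plots. The 4259 control spots had weight 0 in the loess and were then left out, as were spots that the scanner software marked as outliers (a mean of 1.33% per array). Spots of 1 probe were averaged, and 327 probe values left empty were filled with the group mean. Of 30367 probes, 18758 were matched by accession to a gene of the GRCr8 annotation (15715 genes), and the others kept the name in the files. Genes with several probes were represented by the probe of highest mean brightness. A gene was tested if its probe stood well above background in the sample channel on at least 50% of the arrays of at least 1 group. This left 20168 genes in hippocampus, 15883 in cerebellum and 20260 in either tissue. Here and in all counts below, a probe or transcript without a gene name counts as a gene. Named genes made up 12658 of those tested in hippocampus and 10377 in cerebellum. No array held a saturated sample spot.

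Fewer probes stood well above background in cerebellum than in hippocampus. The median sample background was 64 in cerebellum and 26 in hippocampus, and 44.7% to 61.5% of probes stood well above background on cerebellum arrays against 56.1% to 96.9% on hippocampus arrays. The arrays lay on 15 slides of hippocampus and 12 of cerebellum, with none shared and 1 scan day per tissue, so that tissue cannot be told apart from slide set, scanner and software version. A block for scan day was therefore not run. Within a tissue, 15 hippocampus slides and 10 cerebellum slides held more than 1 group. Runs of consecutive animal numbers within a time, parted by a gap of 5 or more, gave 13 cohorts, which are nested in time. Of these, 12 held both severities and 1, at 6 h, held a single mild animal.

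Comparisons used limma (lmFit and eBayes) on log2 ratios with Benjamini-Hochberg adjustment at 0.05, fitted to the 6 groups of a tissue. Tissue was compared within animals, on the hippocampus minus cerebellum difference of each of the 42 animals, so that the animal is the block. The pairing comes from the same animal giving both tissues. Deviations from the group means correlated at a median r of 0.069 (from -0.208 to 0.339) for tissues of 1 animal, and above 0.1 in 16 of 42 pairs, against a median of 0 for tissues of different animals. No files were identical, and the highest correlation of deviations between arrays of a tissue was 0.704.

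The tests of severity, time and tissue, 38 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives added after seeing the data were cohort as a random block, each 6 h cohort of more than 1 animal left out, pineal and telencephalon neuron transcripts as covariates, the arrays with pineal transcripts left out and 2 single arrays left out. The rule takes the 10 genes with the highest and the 10 with the lowest log2 difference among those past the test, or the 5 with the smallest p per direction where fewer than 5 passed, and members of the lists. Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated per list. On simulated data with no shifted list, the preset correlation called 20.0% of lists in hippocampus and 9.7% in cerebellum and the estimated correlation 0 of 370 and 0 of 360, so a call with the preset value alone is weak. Severity was also predicted with a ridge classifier that left out 1 animal at a time. The contrasts of tissue by time and lists of pineal gland and telencephalon neuron genes were added after seeing the data.

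The limma comparisons were tested on simulated data with shuffled arrays, in which 200 genes at a time were shifted by known amounts. With the Benjamini-Hochberg adjustment the share recovered depends on how many genes differ, so it may be lower where few do. At 6 h, shifts of 0.25, 0.5 and 1 on the log2 scale between severities were recovered for 28.4%, 76.1% and 96.7% of shifted genes in hippocampus (20168 genes) and for 14.9%, 85.4% and 99.7% in cerebellum (15883 genes). For the difference of the severity effect between tissues at 6 h the shares were 3.6%, 42.1% and 92.7% (20260 genes). Alternatives covered the scanner's log10 ratio, the authors' table, normalisation of the reference channel, the filter on dim probes, all probes of a gene, array weights, slide, cohort, choroid plexus, pineal and telencephalon neuron transcripts as covariates, single arrays left out and the pairing. A few genes that the rule takes are not reported here, while the counts of named gene results include them.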

Results

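Gene expression was measured in the hippocampus, a forebrain region of memory formation, and in the cerebellum, a hindbrain region of motor control, to ask how mild and moderate traumatic brain injury differ in the 2 tissues over time. In hippocampus, the mild groups held 9, 11 and 11 rats at 6 h, 48 h and 14 d and the moderate groups 9, 11 and 10. In cerebellum, the mild groups held 8, 7 and 6 rats and the moderate groups 8, 7 and 8. Median sample signal per array ran from 67.5 to 289 in hippocampus and from 101 to 240 in cerebellum. Values are log2 differences with their standard error (SE) from limma, and adjusted p is the Benjamini-Hochberg value. No uninjured animals were analysed here, so each comparison is between injured groups.

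In the hippocampus, no gene passed the test between moderate and mild injury. limma called 0 of 20168 genes at 6 h, at 48 h and at 14 d, with 467, 208 and 1178 genes at an unadjusted p under 0.05, and 0 over the mean of the 3 times with 422. Among the genes with the smallest p, Klf10, a transcription factor induced by transforming growth factor beta, had a difference of 0.41 ± 0.10 (SE) at 14 d (adjusted p = 0.773), Rdh10, a retinol dehydrogenase, -0.27 ± 0.07 (SE) at 6 h (adjusted p = 0.999) and Satb1, a chromatin organiser, 0.27 ± 0.09 (SE) at 48 h (adjusted p = 1). Gfap, the intermediate filament of astrocytes, lay between -0.12 and 0.29 over the 3 times, with 95% confidence bounds from -0.62 to 0.82. Nefl, a neurofilament subunit, lay between -0.01 and 0.11 (bounds -0.44 to 0.56), Uchl1, a neuronal deubiquitinase, between 0.00 and 0.02 (bounds -0.19 to 0.19), S100b, an astrocyte calcium-binding protein, between -0.19 and 0.05 (bounds -0.47 to 0.35), and Aif1, a microglial marker, between -0.11 and 0.02 (bounds -0.27 to 0.17). For a change of the severity difference between times, the limma F-test called 0 genes, with 375 at an unadjusted p under 0.05.

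The 17 measured choroid plexus genes, which mark the epithelium that makes cerebrospinal fluid, averaged 0.75 higher after moderate injury at 6 h (adjusted p = 5.54e-07 in camera with the preset correlation, adjusted p = 0.986 with an estimated correlation), and 0 of 17 passed alone. The list mean itself gave p = 0.0734 in an exact two-sided permutation test of the 9 moderate against the 9 mild arrays (0.44 adjusted over 6 such tests). Cell cycle genes had a median of -0.29 at 14 d (adjusted p = 1.14e-06, and adjusted p = 0.986 with an estimated correlation), with 0 of 18 past the test over all genes and 0 adjusted over the list alone. Immediate early genes, which neurons induce upon activity, had a median of 0.11 at 48 h (adjusted p = 3.57e-05, and adjusted p = 0.986 with an estimated correlation), with 0 of 22 past the test over all genes and 0 adjusted over the list alone.

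In the cerebellum, 2 probes without a gene name differed between moderate and mild injury at 6 h, and no named gene passed the test. limma called A_64_P020158, higher by 0.53 (adjusted p = 0.00787), and ENSRNOT00000032073, which fell by 0.56 (adjusted p = 0.033), of 15883 genes, with 1908 at an unadjusted p under 0.05. Both were chosen after their values were seen, and neither passed with the scanner's own log ratio or with slide as a block. At 48 h and 14 d limma called 0 genes, with 778 and 1787 at an unadjusted p under 0.05, and 0 over the mean of the 3 times with 1124. Snap29, a membrane fusion protein, had a difference of 0.34 ± 0.07 (SE) at 6 h (adjusted p = 0.135), Bmal1, a core clock activator, 0.37 ± 0.09 (SE) at 6 h (adjusted p = 0.174), Dnmbp 0.30 ± 0.06 (SE) at 48 h (adjusted p = 0.529) and C1qtnf12, a secreted C1q-like protein, 0.52 ± 0.11 (SE) at 14 d (adjusted p = 0.091). Gfap lay between -0.36 and 0.17 over the 3 times, with 95% confidence bounds from -0.72 to 0.53, and Aif1 between -0.07 and 0.19 (bounds -0.25 to 0.37). Nefl lay between -0.17 and 0.12, Uchl1 between -0.02 and 0.03 and S100b between -0.13 and 0.06. With array weights, limma called 164 genes at 14 d, 34 higher and 130 lower, and the F-test of severity by time called 42 in place of 0 (1841 at an unadjusted p under 0.05).

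Haemoglobin and erythrocyte genes had a median of 0.30 after moderate injury in cerebellum at 6 h (adjusted p = 0.00847 in camera, adjusted p = 0.986 with an estimated correlation), with 0 of 5 past the test over all genes and 2 adjusted over the list alone. Cell cycle genes had a median of -0.16 there (adjusted p = 0.00878, and adjusted p = 0.986 with an estimated correlation), with 0 of 14 past the test over all genes and 2 lower adjusted over the list alone. Over both tissues, camera called 20 of 300 severity tests of lists with the preset correlation and 0 with the estimated one.

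A ridge classifier named the severity of 28 of 61 hippocampus arrays correctly (45.9%), and 67 of 100 labellings, the real one and others permuted within time, did as well. In cerebellum it named 25 of 44 arrays correctly (56.8%), and 23 of 100 labellings did as well.

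Transcripts of the pineal gland, the gland that makes melatonin, appeared on some arrays of each of the 6 hippocampus groups. The mean log2 ratio of 11 pineal genes was above 0 on 19 of 61 hippocampus arrays, with a highest value of 2.89 and a median over all of -0.24. It was above 0 on 31 of 44 cerebellum arrays too, but lay between -0.07 and 0.14 there. Tph1, which makes serotonin in the pineal gland, ran from -1.81 to 6.46 over hippocampus arrays (median -0.96), and Asmt, which makes melatonin, reached 4.49.

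**Figure D1:**
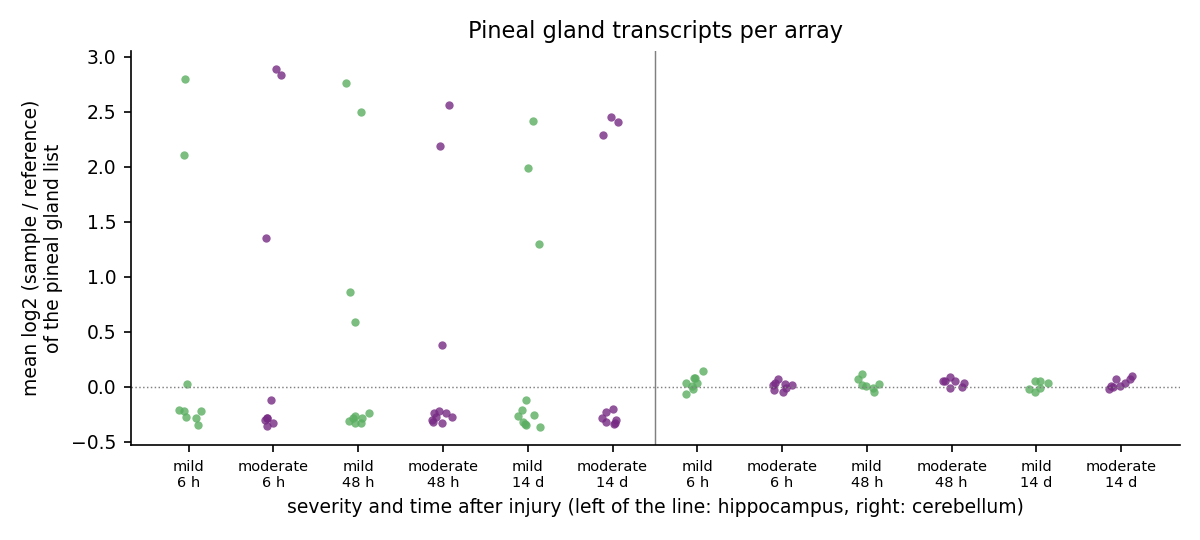
Mean log2 ratio of sample over reference of the pineal gland list on each array (points), by group. Arrays above 0 occur in each of the 6 hippocampus groups, up to 2.89, and the cerebellum arrays lie between -0.07 and 0.14.

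**Figure D2:**
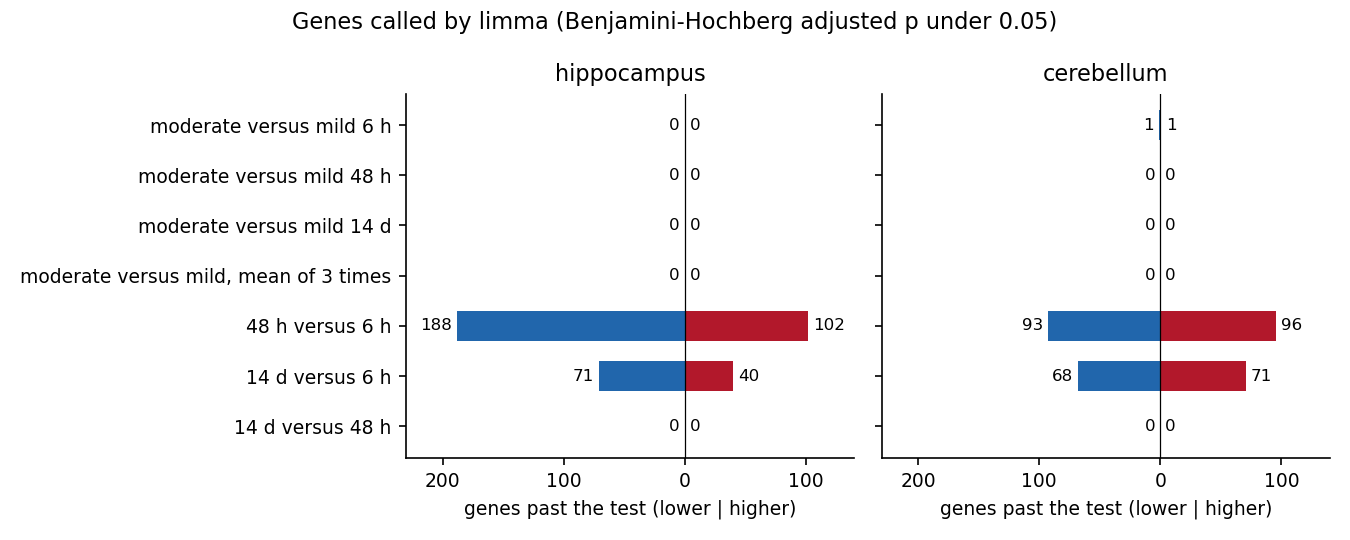
Genes past limma's test at an adjusted p of 0.05 in each comparison of severity and of time. Bars to the right count genes higher and bars to the left genes lower in the first-named group, which were 102 and 188 in hippocampus and 96 and 93 in cerebellum at 48 h versus 6 h, against 0 at 14 d versus 48 h in both tissues.

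Time after injury, in contrast, went with changes in the hippocampus. At 48 h, 290 genes, 225 of them named, differed from 6 h, 102 higher and 188 lower, averaged over both severities. Immediate early genes rose: Arc, a synaptic plasticity gene, by 0.75 ± 0.15 (SE), Egr1, a transcription factor, by 0.68 ± 0.14, Nr4a1, a nuclear receptor, by 0.62 ± 0.11, and Fos, a subunit of the transcription factor AP-1, by 0.49 ± 0.12. Genes that glucocorticoids induce fell, among them Fkbp5, a co-chaperone of the glucocorticoid receptor (-0.50 ± 0.09), the serum and glucocorticoid kinase Sgk1 (-0.66 ± 0.14), and the metallothioneins Mt1 (-0.63 ± 0.13) and Mt2A (-0.64 ± 0.12). None of these 8 genes passed without the 5 arrays of the second 6 h cohort. Arc then had a difference of 0.53 (adjusted p = 0.249), Egr1 of 0.49, Nr4a1 of 0.52 and Fos of 0.34, while Fkbp5 had one of -0.29 (adjusted p = 0.113), Sgk1 of -0.31, Mt1 of -0.33 and Mt2A of -0.40. The mean of the immediate early list was -1 in that cohort, -0.71 and -0.70 in the third and the fourth and -0.35 in the single animal of the first, against -0.67 to -0.26 over the later cohorts. Dbp still fell (adjusted p = 5.5e-09). The largest falls were those of Gpd1, a glycerol-3-phosphate dehydrogenase (2.11-fold, adjusted p = 1.33e-09), Acer2, an alkaline ceramidase (2.01-fold, adjusted p = 4.96e-06), and Dbp, an output gene of the circadian clock (1.86-fold, adjusted p = 3.29e-11).

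Of the 22 immediate early genes, 7 rose and 0 fell at 48 h over all genes tested, and 11 rose adjusted over the list alone (adjusted p = 0.0294 with an estimated correlation). Of 17 glucocorticoid response genes, 7 fell, and adjusted over the list alone 11 fell and 1 rose (adjusted p = 0.0151 with an estimated correlation). Without the second 6 h cohort 0 of the 22 immediate early genes rose over all genes, and adjusted over the list alone 7 rose and 1 fell. Of the 17 glucocorticoid response genes 1 then fell over all genes and 7 adjusted over the list alone. The median of the immediate early list went from 0.23 to 0.17 and that of the glucocorticoid list from -0.31 to -0.15. Of 15 clock genes, Bmal1 rose (0.27 ± 0.07) and 4 fell, including Dbp, Tef (-0.38 ± 0.06) and the repressor Nr1d1 (-0.41 ± 0.09), and adjusted over the list alone 1 rose and 5 fell (adjusted p = 0.00916 with an estimated correlation). Without the second 6 h cohort 0 clock genes rose and 3 fell over all genes, so that Bmal1 did not pass, and 1 rose and 5 fell adjusted over the list alone. Of 18 genes of heat shock and the unfolded protein response, Hspa5, the main chaperone of the endoplasmic reticulum (0.37 ± 0.06), and Sdf2l1 (0.23 ± 0.06) rose and Herpud1 (-0.26 ± 0.06) fell, and adjusted over the list alone 3 rose and 1 fell (adjusted p = 0.53 with an estimated correlation). Mfsd2a, a lipid transporter of the blood-brain barrier, fell (-0.58 ± 0.08), and Cxcl12, a chemokine, rose (0.47 ± 0.11). Lists of cell types were lower at 48 h in camera with the preset correlation alone: the median was -0.175 for 16 pan-neuronal and synaptic genes (adjusted p = 0.000772), -0.217 for 15 myelin and oligodendrocyte genes (adjusted p = 0.00469), -0.203 for 16 glutamate receptor and transporter genes (adjusted p = 0.0081), -0.201 for 14 GABA signalling genes (adjusted p = 0.0082) and -0.105 for 15 resting astrocyte markers (adjusted p = 0.0094). With an estimated correlation adjusted p was 0.886 for the first 4 and 0.813 for the astrocyte markers, and 1 astrocyte marker, the gap junction gene Gjb6 (-0.43 ± 0.10), and no gene of the other 4 lists passed alone. Genes of adjacent forebrain had a median of -0.10 (adjusted p = 0.0302, and adjusted p = 0.68 with an estimated correlation) and microglia and macrophage genes of -0.07 (adjusted p = 0.0438, and adjusted p = 0.886 with an estimated correlation), with 0 past the test over all genes in either.

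At 14 d, 111 genes, 98 of them named, differed from 6 h in hippocampus, 40 higher and 71 lower. Arc (0.79 ± 0.15), Egr1 (0.79 ± 0.14), Egr4 (0.77 ± 0.16) and Nr4a1 (0.71 ± 0.11) rose, and 10 of 22 immediate early genes rose over all genes and 16 adjusted over the list alone (adjusted p = 0.00252 with an estimated correlation). Fkbp5 fell (-0.67 ± 0.09), as did 7 of 17 glucocorticoid response genes, or 10 with 1 risen adjusted over the list alone (adjusted p = 0.00252 with an estimated correlation). Of the clock genes, Bmal1 rose (0.34 ± 0.07) and 4 of 15 fell, with Dbp at -0.74 ± 0.08, and adjusted over the list alone 2 rose and 5 fell (adjusted p = 0.00285 with an estimated correlation). Without the second 6 h cohort, 1 immediate early gene rose and 1 glucocorticoid response gene, Fkbp5 (-0.46), fell over all genes, and adjusted over the list alone 9 immediate early genes rose and 1 fell and 6 glucocorticoid response genes fell. Of the clock genes 0 then rose and 2 fell over all genes, or 2 and 5 adjusted over the list alone. Pan-neuronal and synaptic genes had a median of -0.10 (adjusted p = 0.0119, and adjusted p = 0.886 with an estimated correlation). Cd93, an endothelial and myeloid receptor, rose (0.47 ± 0.09). Between 14 d and 48 h limma called 0 genes, with 913 at an unadjusted p under 0.05.

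The hippocampus counts depended on how arrays were grouped. With slide as a block limma called 131 genes at 48 h (67 higher, 64 lower) and 154 at 14 d (91 higher, 63 lower), and with cohort as a random block 190 and 67. It called 23 and 14 without the 5 arrays of the second 6 h cohort and 36 and 25 without the 19 arrays with pineal transcripts. Leaving out the third 6 h cohort instead gave 597 and 333, and leaving out the fourth 366 and 125. With array weights it called 486 and 206. The scanner's log ratio split the 48 h calls into 151 higher and 173 lower, and the authors' table into 243 higher and 125 lower, where only the former had been centred on each array's median. On every one of the 9 slides that held both 6 h and later arrays Dbp was lower later (median -0.75, from -1.13 to -0.38), the glucocorticoid list mean was lower (median -0.17) and the immediate early gene mean was higher (median 0.41).

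In the cerebellum, 189 genes, 160 of them named, differed at 48 h from 6 h, 96 higher and 93 lower. Mmp14, a membrane-bound matrix metalloproteinase, rose by 0.80 ± 0.08 (SE) and Cd93 by 0.75 ± 0.09, and the immediate early genes Nr4a2 by 0.99 ± 0.25 and Fos by 0.81 ± 0.21. Dbp fell (-0.80 ± 0.08), together with the clock output gene Tef (-0.75 ± 0.10), Nr1d1 (-0.67 ± 0.11), Gpd1 (-0.68 ± 0.10), and Fibin (-0.71 ± 0.09). Of 15 glucocorticoid response genes, 7 fell and 0 rose over all genes, and 12 fell adjusted over the list alone, among them the sulfotransferase Sult1a1 (-0.59 ± 0.08) and the transcription factor Klf9 (-0.46 ± 0.07; adjusted p = 0.0294 for the list with an estimated correlation). Without the 4 arrays of the second 6 h cohort, 2 of the 15 fell over all genes, Sult1a1 (-0.49) and Klf9 (-0.34), and 7 adjusted over the list alone. The list's median went from -0.31 to -0.17. The list mean at 6 h was 0.42 in that cohort and -0.07 and -0.01 in the third and the fourth, against -0.22 to -0.12 over the 48 h cohorts. Of 14 clock genes, Nfil3 (0.32 ± 0.07) and Cry1 (0.34 ± 0.08) rose and 4 fell, and adjusted over the list alone 3 rose and 4 fell (adjusted p = 0.0456 with an estimated correlation). Of 18 immediate early genes, 2 rose over all genes and 6 adjusted over the list alone (adjusted p = 0.266 with an estimated correlation). Without the second 6 h cohort 1 clock gene rose and 4 fell over all genes, while 0 immediate early genes passed over all genes and 6 rose adjusted over the list alone. Nr4a2 then had a difference of 0.71 and Fos of 0.64, and the list's median went from 0.13 to 0.12. The fibroblast genes Dcn (0.37 ± 0.06) and Col15a1 (0.33 ± 0.07) rose among 13 of the leptomeninges and fibroblast list, with 3 risen adjusted over the list alone (adjusted p = 0.813 with an estimated correlation). Of 17 cholesterol synthesis genes, Stard4 (-0.25 ± 0.04) and Insig1 (-0.27 ± 0.07), which regulates the pathway, fell, and 3 fell adjusted over the list alone (adjusted p = 0.813 with an estimated correlation).

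At 14 d, 139 cerebellar genes, 120 of them named, differed from 6 h, 71 higher and 68 lower. Nr4a2 (1.00 ± 0.25), Mmp14 (0.70 ± 0.08) and Nfil3 (0.45 ± 0.07) rose, and Abcg2, an efflux transporter of the blood-brain barrier (-0.94 ± 0.16), Dbp (-0.79 ± 0.08) and the glucocorticoid-induced Tsc22d3 (-0.64 ± 0.11) fell. Of 15 glucocorticoid response genes 3 fell over all genes and 11 adjusted over the list alone (adjusted p = 0.0294 with an estimated correlation), or 3 and 5 without the second 6 h cohort, with a median of -0.16 in place of -0.32. Of 14 clock genes 2 rose and 3 fell, or 4 and 5 adjusted over the list alone (adjusted p = 0.226 with an estimated correlation), and without that cohort 2 rose and 2 fell over all genes. Of 18 immediate early genes 2 rose over all genes and 6 adjusted over the list alone (adjusted p = 0.53 with an estimated correlation), or 0 and 5 without that cohort, with a median of 0.11 and then 0.12. Among the cell type lists, 16 choroid plexus genes had a median of 0.18 (adjusted p = 0.011, and adjusted p = 0.893 with an estimated correlation) and 19 microglia and macrophage genes of 0.105 (adjusted p = 0.0119, and adjusted p = 0.68 with an estimated correlation), with 0 past the test over all genes in either and 0 and 3 risen adjusted over the list alone. Of 13 leptomeninges and fibroblast genes, with a median of 0.11, Dcn rose (0.28 ± 0.07; adjusted p = 0.68 for the list with an estimated correlation), and of 12 antigen presentation genes, with a median of 0.17, Psmb9, a subunit of the immunoproteasome, rose (0.33 ± 0.07; adjusted p = 0.426 for the list with an estimated correlation). Adjusted over the list alone, 3 and 4 rose. Of 17 cholesterol synthesis genes 3 fell over all genes, Stard4 and Insig1 among them, and 5 fell adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). Between 14 d and 48 h limma called 0 genes, with 1180 at an unadjusted p under 0.05. With slide as a block, limma called 164 genes at 48 h and 11 at 14 d, with cohort as a random block 95 and 67. Without the 4 arrays of the second 6 h cohort it called 57 and 70. Leaving out the third instead gave 370 and 161, and leaving out the fourth 227 and 210. Array weights also raised the 14 d count, as given below. Dbp was lower later on all 7 slides that held both 6 h and later arrays (median -0.87).

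**Figure D3:**
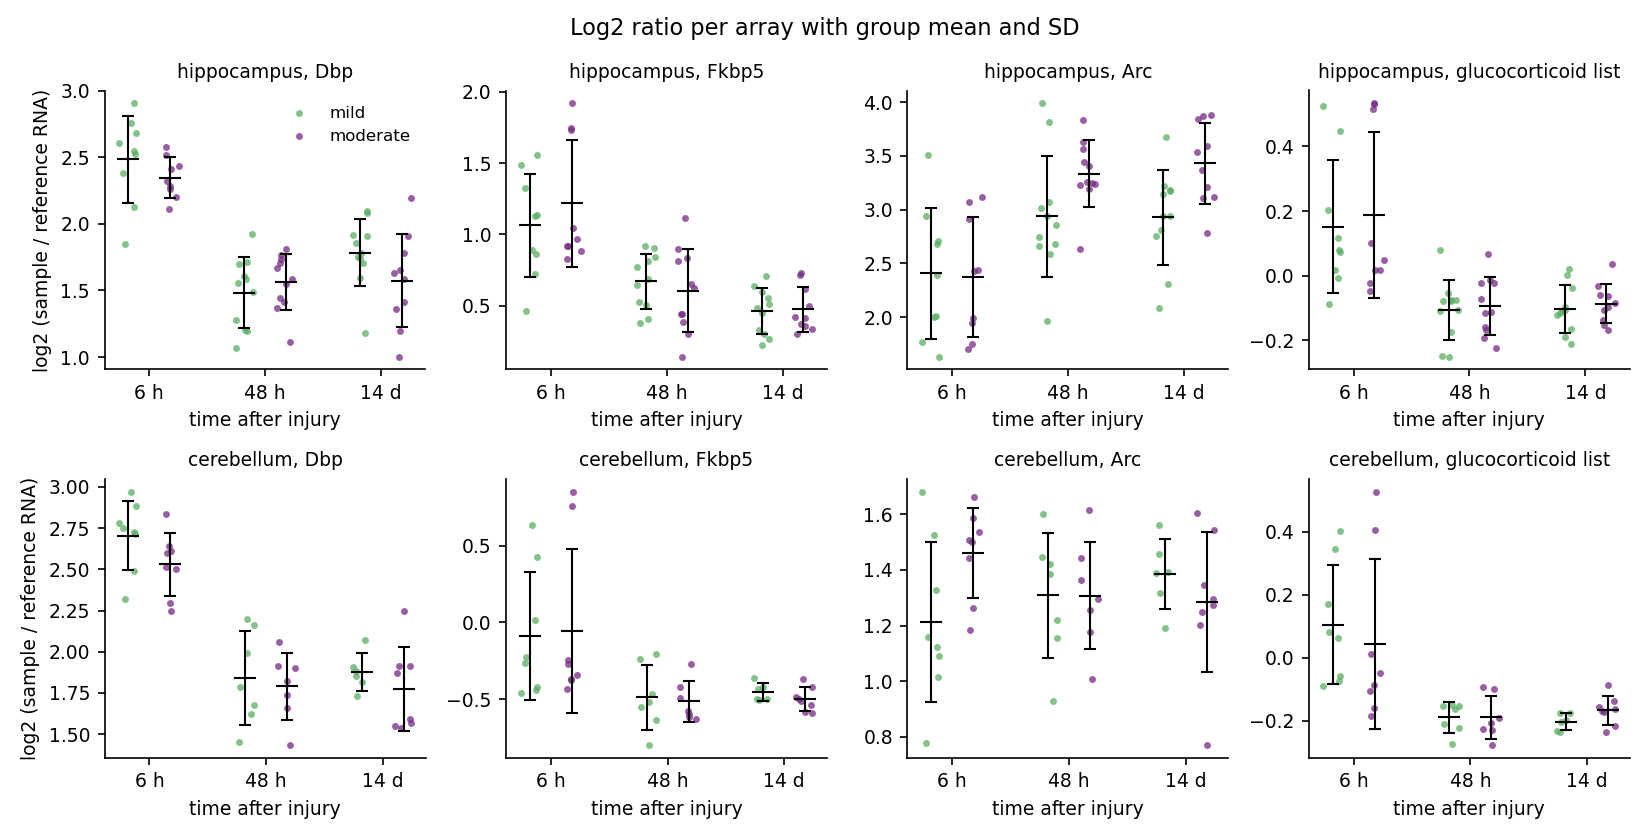
Log2 ratio of sample over reference for Dbp, Fkbp5, Arc and the mean of the glucocorticoid response list on each array, by time after injury and severity (points), with the group mean (bar) and SD (whisker). Dbp was 0.90 lower at 48 h than at 6 h in hippocampus and 0.80 lower in cerebellum.

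The later times shared many genes. In hippocampus, 25 genes were higher and 51 lower than at 6 h at both later times, against 0.202 and 0.662 for independent lists, and in cerebellum 34 and 39, against 0.429 and 0.398. Both comparisons use the same 6 h arrays. Unchanged groups simulated against shared arrays gave at most 0 shared calls in 20 draws. Groups without any change yield few calls to share, so this count cannot tell what the shared arrays contribute. With the 6 h arrays divided between both comparisons, which also leaves each with fewer arrays, the comparisons called a median of 17.5 and 51.5 genes in hippocampus and 54 and 38 in cerebellum. The shared calls then had a median of 9.5 (from 2 to 16) and 13.5 (from 9 to 19). Across genes, which are not independent replicates, the covariance of the log2 differences was 0.00638 in hippocampus against 0.0031 simulated, and 0.00728 in cerebellum against 0.0034. Hippocampus and cerebellum shared 12 higher and 30 lower genes at 48 h, against 0.59 and 1.04 for independent lists, and 9 and 18 at 14 d, against 0.171 and 0.272. The tissues come largely from the same animals and cohorts, so independent lists are no value for chance here. With the times of the animals permuted 20 times, the tissues shared at most 0 calls at either time. Permuted times left a median of 0 called genes in each tissue, so few calls could be shared and this count decides nothing. These permutations also moved single animals and took no account of cohort. Across genes the covariance of the log2 differences of the tissues was 0.00419 at 48 h, against a highest value of 0.00253 over the same permutations. It was 0.00296 at 14 d, below the highest permuted value of 0.00375. Cd93, Etv5, Rhobtb1 and Tm4sf1 were higher than at 6 h in both tissues at both later times, and 16 genes were lower, among them Dbp, Tef, Gpd1, Klf9, Sult1a1, Tsc22d3 and Mfsd2a. Tested within a severity, limma called 16 genes in mild and 22 in moderate injury at 48 h versus 6 h in hippocampus and 5 and 25 at 14 d versus 6 h. In cerebellum it called 68 and 12, and then 24 and 24.

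The tissues themselves differed in most genes. Within the 42 animals with both tissues, limma called 15543 of 20260 genes, 8449 higher in hippocampus and 7094 higher in cerebellum. Hippocampus was higher in Icam5, a neuronal adhesion molecule of the telencephalon (86.5-fold, 6.44 ± 0.07, well above background on 37 of 44 cerebellum arrays), and Cck, the neuropeptide cholecystokinin (26.8-fold, 4.74 ± 0.23). Cerebellum was higher in Car8, a Purkinje cell protein (98.6-fold, -6.62 ± 0.05), Gabra6, the GABA receptor subunit of granule cells (well above background on 44 of 44 cerebellum and 5 of 61 hippocampus arrays, adjusted p = 3.63e-52), and Pcp2, another Purkinje cell gene (adjusted p = 1.73e-46). At Pcp2 the log2 difference of ratios was -4.23 ± 0.05 (SE), while before normalisation the log2 sample signal differed by -7.81 and that of the common reference by -4.31 (hippocampus minus cerebellum). The median reference difference over all probes was 0.05, so the ratio gives no size for this gene. The reference signal at Cck was 1.55 higher in hippocampus, against a sample difference of 5.82. Of the cell type lists, 13 of 13 granule cell genes and 14 of 15 Purkinje cell genes were higher in cerebellum, and 10 of 14 hippocampal subfield genes, 15 of 19 neuropeptide and neurotrophin genes and 17 of 21 microglia and macrophage genes in hippocampus, with Aif1 at 0.67 ± 0.03. Cholesterol synthesis genes were higher in hippocampus in 15 of 19 cases and ribosomal protein genes in cerebellum in 18 of 25. Tissue cannot be told apart from slide set, scanner and software version, and the scanner's log ratio turned the sign of 479 of the 15543 genes, none of those named.

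**Figure D4:**
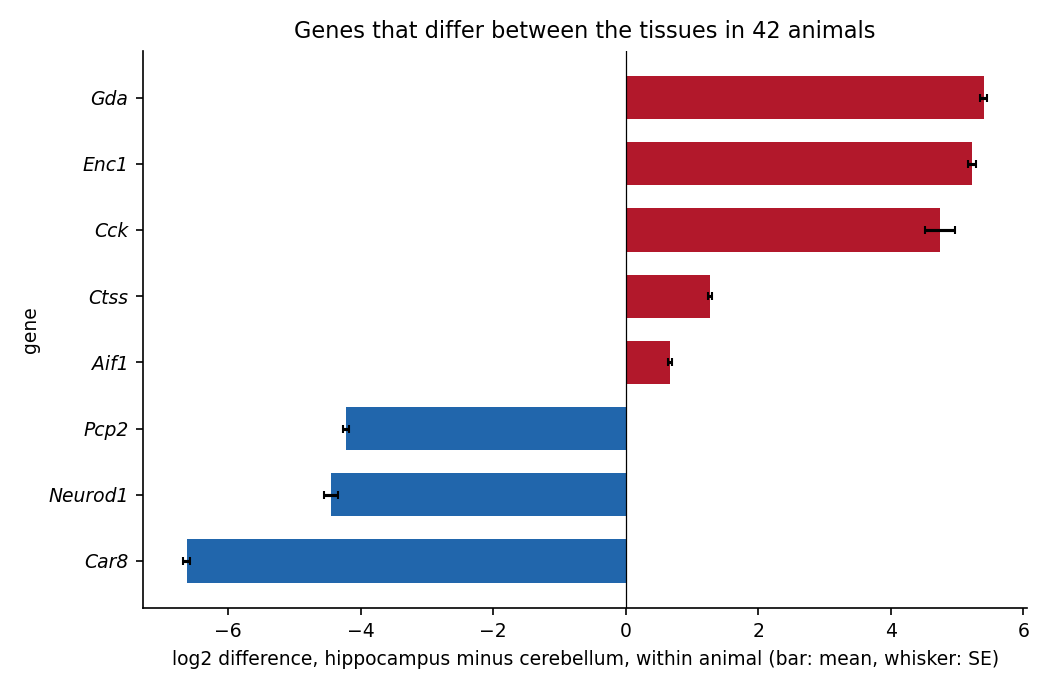
Log2 difference of hippocampus minus cerebellum within animals (bars), with the SE (whiskers), for 8 genes well above background in the sample channel on all arrays of both tissues. Gda and Enc1 reach 5.40 and 5.23 toward hippocampus, and Car8 and Neurod1 reach -6.62 and -4.45 toward cerebellum. The reference signal of Neurod1 was well above background on only 3 of 61 hippocampus and 34 of 44 cerebellum arrays, so its size is uncertain. The bar of Pcp2 gives no size, as its reference signal differed by -4.31.

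No gene passed the test for a severity effect that differs between the tissues. limma called 0 of 20260 genes at 6 h, 48 h and 14 d and over their mean, with 1103, 627, 665 and 677 at an unadjusted p under 0.05. In the simulations with 200 shifted genes, 42.1% of differences of 0.5 on the log2 scale were recovered at 6 h, 36.1% at 48 h and 35.5% at 14 d. The share may be lower where fewer genes differ. The effect of time, a contrast added after seeing the data, differed between the tissues in 1 gene at 48 h versus 6 h (1302 at an unadjusted p under 0.05), in 13 at 14 d versus 6 h and in 0 at 14 d versus 48 h (647 at an unadjusted p under 0.05). Both counts against 6 h were higher with array weights, the scanner's log ratio and the authors' table, as given below.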

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

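The contrasts of tissue by time and the tests of slide, of cohort and of time of day in this part were chosen after the results were seen.

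The mean log2 ratio of the choroid plexus list stood apart on 1 array in each of 2 cerebellum groups. Replicate 4 of the mild 14 d group was the highest of 6 at 1.79, with the next at 1.34, and replicate 3 of the mild 6 h group was the lowest of 8 at -0.33, with the next at 1.13. Of 54 tests, of 3 genes and 3 list means in each of the 9 groups of 4 to 10 samples, 2 found a far sample, and chance gives about 1 in 20. Choroid plexus values also ran widely in hippocampus, from -0.35 to 2.59 in the mild 6 h group.

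The change from 6 h differed between hippocampus and cerebellum in 1 gene at 48 h and in 13 genes at 14 d. The gene at 48 h was the unnamed transcript ENSRNOT00000026303, higher by 1.09 in hippocampus relative to cerebellum. At 14 d, the vascular peptide Apln (0.58) and Fibin (0.54) were among 8 genes with a higher difference in hippocampus, and Gpd1 (-0.54), the ubiquitin ligase Cblb (-0.58) and the kinase subunit Pik3r1 (-0.46) among 5 with a lower one. Another of the 8, Egr2, was well above background on 0 of 44 cerebellum arrays, so its change there was not measured. Of 100 splits of the animals, the real one included, 2 gave as many genes at each contrast. The splits take no account of cohort and do not repeat the choice of these contrasts after seeing the data, so chance is not excluded. Assigning whole cohorts to the times gave as many genes in 4 of 10 assignments at 48 h (1 real, 1 highest other) and in 1 of 10 at 14 d (13 and 0), and 10 are too few for a share under 0.05. The highest other splits of single animals gave 14 genes at 48 h and 258 at 14 d. The latter may point to a structure of the animals. What that split follows was not tested, and such a rare count may also come by chance.

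For the genes that differed between 6 h and the later times, the 48 h differences of the called genes kept a median of 0.988 of their size in hippocampus (quartiles 0.863 and 1.09) and 1.09 in cerebellum (quartiles 0.999 and 1.17) with slide as a block. The 14 d differences kept 1.03 (quartiles 0.908 and 1.20) and 0.95 (quartiles 0.82 and 1.09), which argues against slide as the whole cause at either time, and the fall from 139 to 11 calls at 14 d in cerebellum goes with an SE that was 1.33 times as large (median). Without the second 6 h cohort the sizes were 0.779 (quartiles 0.695 and 0.885) and 0.841 (quartiles 0.744 and 0.935), but 23 of the 290 and 53 of the 189 genes were still called; the 23 and 57 calls in all lay below each of 50 random sets of as many arrays left out, as did 14 in hippocampus at 14 d, while for the 70 in cerebellum at 14 d 6 of 50 sets gave as few, and the genes had been chosen with that cohort included, so how much it contributes stays open. Its glucocorticoid list mean was 0.51 in hippocampus and 0.42 in cerebellum against 0.03 and -0.07 in the third cohort, while its Dbp mean in hippocampus was 2.39 against 2.46. Clock genes in phase with Bmal1 moved above those in phase with Dbp by 0.47 in hippocampus (9 of 10 genes in the direction) and 0.72 in cerebellum (10 of 10), consistent with another time of day of collection at 6 h, for which the clock times are not given in the sources used here, and age, injury and handling stay open as untested.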

How the results depend on the processing

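Cohort as a random block, the 6 h cohorts left out, the pineal and telencephalon neuron settings and those without HC_mild_6h replicate 5 or CB_moderate_14d replicate 6 were chosen after seeing the data. Probes of both signs occurred among called genes that had a gene name and several probes. They were found in 16 of 60 such genes in hippocampus at 48 h and 1 of 25 at 14 d versus 6 h. In cerebellum they were found in 2 of 27 and 1 of 23. None of the 6, 7, 7 and 9 such genes picked for the text had them. No gene picked for the text that passed its test turned its direction under any setting, read at its brightest probe. Most called results of these picked genes over time lost their call in some setting. In hippocampus 6 of 25 kept it in all settings run at 48 h versus 6 h, and 6 of 24 did at 14 d. In cerebellum 13 of 24 and 5 of 21 did, and between tissues 18 of 18. Quantile normalisation of the reference channel leaves the log ratios as they were and so tests nothing. Array weights moved the counts to 486 (hippocampus 48 h versus 6 h) and 206 (14 d versus 6 h), to 10 (cerebellum severity 6 h), 164 (severity 14 d), 281 (14 d versus 6 h) and 42 (severity by time), and to 3 for tissue by severity at 6 h and 18 and 163 for tissue by time at 48 h and 14 d. Slide as a block gave 131 in hippocampus at 48 h versus 6 h, and in cerebellum 0 for severity at 6 h and 11 at 14 d versus 6 h. Cohort as a random block gave 190 and 67 in hippocampus and 95 and 67 in cerebellum at 48 h and 14 d versus 6 h. Leaving out the second 6 h cohort gave 23 and 14 in hippocampus and 57 and 70 in cerebellum, leaving out the third 597 and 333 in hippocampus and 370 in cerebellum at 48 h, and leaving out the fourth 210 in cerebellum at 14 d. Without the 19 arrays with pineal transcripts hippocampus gave 36 and 25, where 50 random sets of 19 arrays left out gave medians of 72 and 40, so fewer arrays account for much of the fall. The scanner's log ratio and the authors' table each gave 0 for cerebellum severity at 6 h, and 8 and 7 (48 h) and 20 and 27 (14 d) for tissue by time. Cohort as a fixed block gave 3 for cerebellum severity at 14 d and 5 for severity by time, and a fit to only the groups compared gave 1 for severity at 6 h and 1 at 14 d. The stricter filter left 1 gene for cerebellum severity at 6 h and 9597 between tissues, with fewer genes tested. Cerebellum 14 d versus 48 h gave 1 gene without CB_mild_48h replicate 7, whose file name carries the other severity's tag, and 2 without CB_moderate_14d replicate 6. Gene lists for severity moved from 20 calls to 0 with an estimated correlation, 31 with the scanner's log ratio and 33 with slide as a block, and those for time from 43 to 9 with an estimated correlation. Except where fewer arrays or genes were tested, the cause was not tested. Ignoring the pairing by animal (no block) gave 16097 genes between tissues and 0 for tissue by severity. The animal as a random block gave 0 for the latter too. These fits used all 105 arrays and not only the 42 animals with both tissues. No count moved by over 1.5 times, but the effect of pairing cannot be told apart from that of the added arrays. Tissue by time was not run without the pairing. The telencephalon neuron covariate changed no call of the 57 cerebellar results of the genes picked for the text. Scan day was not run as a block.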

Other observations

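The tests of explanations and the readings of the splits in this part were chosen after the results were seen, while array weights and slide as a block had been planned.

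Members of other gene lists differed between the tissues in both directions, with no test of the lists themselves. Genes of oxidative stress and metal response were higher in hippocampus in 12 of 19 cases and in cerebellum in 1, extracellular matrix and axon guidance genes in 12 and 6 of 18 and immediate early genes in 17 and 2 of 22, with Arc 3.02-fold and Dusp6 4.06-fold higher. Leptomeninges and fibroblast genes were higher in cerebellum in 9 of 14 cases and in hippocampus in 3, resting astrocyte markers in 9 and 5 of 15 and oxidative phosphorylation genes in 13 and 7 of 27. Of 17 choroid plexus genes, 12 did not pass the test. In hippocampus at 48 h versus 6 h, the metallothioneins Mt1 and Mt2A and Srxn1, an antioxidant reductase (-0.22 ± 0.05 SE), fell in the oxidative stress and metal response list, while Mt3 had a difference of -0.20 ± 0.13 (SE) that did not pass.

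Pineal gland transcripts on some hippocampus arrays were weighed as a pattern of their own. The 11 pineal genes varied together, with 86.1% of their variance on 1 component, which goes with pineal gland in some dissected samples. The highest value among random sets of as many genes was 45.2%. The list was added after seeing the data, so the random sets are a weak comparison. Slide held 24.9% of the variance of the list mean (permutation p = 0.38) and injury group 1.0% (permutation p = 0.99), and neither p excludes a contribution. With the list as a covariate, 283 of the 290 genes of hippocampus 48 h versus 6 h were still called.

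Array weights called 164 genes between moderate and mild injury in cerebellum at 14 d, 130 of them lower after moderate injury, such as Nr1d1 (-0.65) and Aplp2 (-0.60). Leaving out replicate 6 of the moderate group, the array of lowest weight at 14 d (0.31), without weights gave 0 genes, which argues against that array alone hiding a difference. With slide as a block besides the weights, the differences kept a median of 1.09 of their size and 306 genes were called, which argues against slide. Of 100 splits, the real one included, 1 gave as many genes, but the highest other split gave 158. This comparison was taken up after its 164 calls were seen, out of many settings and comparisons. The splits do not repeat that choice, so chance is not excluded. No setting without weights called over 3 genes there. A difference between severities in cerebellum at 14 d may exist, but stays a hypothesis that rests on this weighting.

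Replicate 5 of the mild 6 h hippocampus group, the only animal of its cohort, had log2 ratios of 3.51 for Arc, 1.85 for Dbp and 0.46 for Fkbp5, where the other 6 h cohorts had means of 1.82 to 2.56, 2.39 to 2.49 and 0.94 to 1.69. The cohort means at the later times ran from 2.83 to 3.62 for Arc, 1.35 to 1.98 for Dbp and 0.29 to 0.92 for Fkbp5, so its 3 values lie within those of the later times. Whether its time label is right was not tested, and without it limma called 264 genes at 48 h and 126 at 14 d versus 6 h.

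Splits of the arrays into groups of the same sizes were counted for each comparison, as the number of 100 splits, the real one included, with a result as large. For severity in hippocampus all 100 did at 6 h, 48 h, 14 d, over the mean and for severity by time. All had 0 real calls, and the highest others gave 8, 210, 1, 1 and 1. With 0 real calls every split gives as many, so such shares decide nothing, here and below. For cerebellum all 100 did at 48 h, 14 d, over the mean and for severity by time, with highest others of 8, 1, 2 and 13. At 6 h 4 did, with 2 real calls and a highest other of 12. That share is the smallest of the many severity counts split without array weights and is not adjusted for their number. Neither probe passed with slide as a block, of which the splits take no account, so chance is not excluded there. For tissue by severity all 100 did at 6 h, 48 h, 14 d and over the mean, with highest others of 0, 12, 3 and 754. Splits that called 210 and 754 genes, where the median split called 0, may point to a structure of the samples. What these splits follow was not tested, and such rare counts may also come by chance. The severity lists gave as many calls in 91 splits (20 real, 66 highest other), and the classifier did as well in 67 splits for hippocampus (45.9% real, 68.9% highest other) and 23 for cerebellum (56.8% and 70.5%), so chance could not be excluded for any of these 3.

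For time, 2 splits gave as many genes in hippocampus at 48 h versus 6 h (290 real, 345 highest other) and 2 at 14 d versus 6 h (111 and 123), and 1 in cerebellum at each (189 and 49, 139 and 10), so chance could be excluded for splits of single animals, which take no account of cohort. At 14 d versus 48 h all 100 did in hippocampus (0 and 0), in cerebellum (0 and 44) and for tissue by time (0 and 19). With a real count of 0 this was fixed in advance, also for cohorts assigned at 14 d versus 48 h below. These shares decide nothing. The time lists gave as many calls in 7 splits (43 and 52), so chance could not be excluded, and with an estimated correlation in 1 (9 and 1), so it could. With whole cohorts exchanged between the 3 times, 19 of 100 assignments gave as many list calls (43 and 59), so chance could not be excluded, and with an estimated correlation 1 did (9 and 7), so it could. Assigning whole cohorts to the times, as a split that follows a batch, gave as many genes in 1 of 100 assignments in hippocampus at 48 h versus 6 h (290 and 260), so that chance could be excluded there too. It did so in 3 of 35 at 14 d versus 6 h (111 and 171), where chance could not be excluded and cohort as a random block gave 67, and in all 100 at 14 d versus 48 h (0 and 120). In cerebellum 1 of 10 did at 48 h (189 and 122) and 1 of 10 at 14 d (139 and 11). With 10 assignments no share can fall under 0.05. At 14 d versus 48 h 10 of 10 did (0 and 22), as for tissue by time (0 and 0), which the real count of 0 fixed in advance. Turning the sign of the tissue difference in random animals gave as many genes in 1 of 100 draws (15543 real, 10341 highest other), so chance could be excluded.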
